A study of Rattus norvegicus with 8 samples.

How the data were processed

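Liver RNA of male Sprague-Dawley rats, an outbred laboratory strain, was measured on Affymetrix rat expression arrays, 1 array per liver. Per the labels, 4 arrays came from rats on an iron-deficient diet and 4 from rats on a control diet, each described as a biological replicate, and biotin-labelled cRNA was made from 2 ug of total RNA. The deposited table holds 1 value per probe set and array for 31099 probe sets. The deposited values are on a log2 scale, a unit read from the values themselves, which run from 5.32 to 16.1. How probes were summarised and arrays normalised by the authors is not given in the sources used here.

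The deposited values are on a common scale across arrays, with array medians from 7.1199 to 7.1207 on the log2 scale and no centring of genes visible. Differences between arrays are compressed, and by an amount that differs between probe sets. The median absolute difference between the group means was 4.49e-06 and the median within-group SD 7.82e-06. Of 9597 pairs of probe sets for the same gene, 449 had values that correlated above 0.9 across the 8 arrays, and in those pairs the SD differed by a median factor of 2.73. A deposited difference is therefore not a fold change, and sizes cannot be compared between probe sets. Each difference is given with its SE from limma, together with the standardised difference, which is the difference divided by the within-group SD. The number of arrays, 4 per group, limits the precision.

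Probe sets were paired with genes through the platform annotation, with symbols updated through gene identifiers. Of the probe sets, 57 were hybridisation or RNA controls and were left out, which left 31042. Of these, 20826 had 1 symbol, 436 had several and 9780 had none, and 20758 of those with 1 symbol were matched by gene identifier. A gene was represented by its probe set with the highest mean over all arrays, which gave 14217 genes, 4525 of them with more than 1 probe set. No gene was named from a probe set with several symbols.

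The comparison was iron-deficient minus control, fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3 without trend or robust options and without a replicate block. Benjamini-Hochberg adjustment covered all tested probe sets, with a threshold of 0.05. Genes were counted from the same fit. Gene lists were tested with camera of limma at a preset correlation of 0.01, adjusted over 23 gene lists and 8 cell type marker lists with at least 5 measured members, and beside it with an estimated correlation and with fry. Counts of members are also given adjusted over the list alone.

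The lists, the tests and the rule for naming genes were fixed before the data were examined. The rule named, first, up to 12 genes per direction past the threshold whose groups did not overlap. It always named Tfrc, Hamp, Hmox1, Fth1, Alas1, Epo and Igfbp1. From each list it named up to 4 members past the threshold or, where none passed, the 2 with the largest absolute difference, as values. The rule ranks deposited differences and was fixed before their compression was seen, so the members it names are not always those with the largest standardised differences. Fth1 was not analysed here. Other genes that passed only when adjusted over their list alone, and those described as chosen after their values were seen, fall outside the rule.

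The scripts were tested on simulated data with the real spread of 31042 probe sets. Of 50 probe sets changed by 2, 4, 8 and 16 within-group SDs each, limma recovered 8%, 32%, 98% and 100%, with 10 false calls. Of 20 simulated lists of 25 genes among 14217, camera called 1 higher with no shift, 16 with a shift of 0.5 SD and 20 with a shift of 1 SD. Lists called lower were not counted, so false calls with no shift may be understated. The simulated genes varied independently, so this does not test camera where members of a list vary together. Other splits of the 8 real arrays into 4 and 4 gave up to 13 called lists of 31, so its p-values may be too small. With 20% of probe sets changed by 2 SD, 224 probe sets passed and 5206 had an unadjusted p under 0.05.

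Alternatives were quantile normalization, median centring, leaving out the lowest 25% of probe sets, each array left out, a replicate block, other variance models, the mean of all probe sets of a gene, a minimum of 1.5-fold and other set tests.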

Results

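Hepatic gene expression was measured in 8 rats at 7 weeks of age, 4 fed a diet without added iron and 4 fed the matching control diet. Per the labels, the diets were given to 7 and 6 rats, livers were taken on day 17 after 1.5 h of feeding, and blood hemoglobin in the iron-deficient group had then reached 42% of the control level. The labels do not say which rats gave the arrays. Values for 31042 probe sets, representing 14217 named genes, were compared between the groups. The first principal component of the scaled values held 23.6% of the variance and the second 16.7%.

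The comparison asked which hepatic transcripts differ under dietary iron deficiency. Tfrc, the transferrin receptor through which cells take up iron, rose, and Hamp, which encodes the iron-regulating hormone hepcidin, was lower in all 4 iron-deficient livers. Genes of cholesterol synthesis and of the hypoxia response rose as groups. Endothelial and stellate cell markers also rose as groups, but neither list was called under quantile normalization. With the Hamp probe set left out of it, the endothelial list was called and the stellate list was not. Subunits of the respiratory chain fell as a group in the values as deposited, but turned higher under quantile normalization. When that normalization was run without the Hamp probe set, the subunits stayed lower as a group but were not called. Another grouping of the 8 arrays gave an absolute shift at least as large for them. Overlap between the groups was absent for 2011 probe sets, or 6.48%, where chance gives 2.86%.

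In limma, 10 probe sets passed the threshold, 7 higher and 3 lower, and 6 genes, 3 higher and 3 lower. At an unadjusted p under 0.05 there were 3539 probe sets, 1615 higher and 1924 lower, where 1552 were expected by chance. Tfrc rose by 0.0373 ± 0.00145 on the deposited log2 scale (SE, n = 4 per group), a standardised difference of 17.4, with an adjusted p of 0.00120 in limma. A second Tfrc probe set rose by 0.0854 ± 0.00600 (limma adjusted p = 0.0183). Fgf23, which encodes a phosphate-regulating hormone, rose by 0.00187 ± 1.05e-04, with a standardised difference of 12.0 (limma adjusted p = 0.00656). Its means of 6.186 in iron-deficient and 6.184 in control livers lie below the 25th percentile of the arrays (6.55), so expression above background was not shown. Adam23, a membrane protein of the disintegrin family, rose by 0.00448 ± 3.30e-04 (limma adjusted p = 0.0213). Ppp1r10, a regulatory subunit of protein phosphatase 1, fell by 0.00264 ± 2.24e-04 (limma adjusted p = 0.0376). Higd2a fell by 2.66e-05 ± 2.27e-06 and Arrdc1 fell by 1.75e-05 ± 1.39e-06, with limma adjusted p of 0.0376 and 0.0298, but Higd2a turned higher under quantile normalization. Both also turned under median centring, which follows from their size alone, since centring takes the same -5.06e-05 off every difference. The other probe sets past the threshold were further ones for Jam2 and Adora2a and 1 without a paired symbol, named here after their values were seen. Their differences were 0.00173 ± 5.98e-05, 0.00472 ± 3.21e-04 and 0.172 ± 0.00867. Tfrc was the only one of the 6 genes to keep its call whichever array was left out, with limma adjusted p from 0.00401 to 0.0168. Fgf23 lost it without iron-deficient replicates 2 (limma adjusted p = 0.0508) and 4 (0.0609), and the other 4 genes lost it without at least 6 of the 8 arrays.

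Among 28 measured genes of iron transport, storage and sensing, 17 were higher and 11 lower. Camera did not call the list (adjusted p = 0.0686), and Tfrc was its only member past the threshold over all genes. Hamp had means of 7.87 ± 1.81 in iron-deficient and 16.02 ± 0.0514 in control livers (SD, n = 4 each). The difference of -8.16 ± 0.864 had a limma adjusted p of 0.0735, since iron-deficient replicate 2 read 10.58 where the other 3 read 6.98, 6.99 and 6.93. Control values of 15.991 to 16.099 lie about at the limit of a 16-bit scan and those 3 below the array medians, so saturation and background were not excluded and the size is not exact. Without iron-deficient replicate 2, left out here for its own Hamp value, the difference was -9.06, with a limma adjusted p of 2.79e-08. With any other single array left out, the limma adjusted p was from 0.121 to 0.231. Adjusted over the list alone, 8 members passed, 5 higher and 3 lower. Beside Tfrc and Hamp these were Slc11a2 (1.10e-04 ± 1.92e-05), Id1 (4.41e-04 ± 9.33e-05), Bmp6 (5.24e-06 ± 1.32e-06) and Cybrd1 (6.60e-06 ± 1.99e-06), which were higher, and Fbxl5 (-4.35e-05 ± 8.42e-06) and Steap3 (-8.72e-05 ± 2.64e-05), which were lower. Slc11a2 and Bmp6 turned lower under quantile normalization and Fbxl5, by its size alone, higher under median centring, and the 4 probe sets of Bmp6 disagreed, with another at -2.65e-04 ± 2.66e-05.

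Cholesterol synthesis and uptake rose as a list, with 20 of 22 measured members higher (camera adjusted p = 7.27e-09, and adjusted p = 0.0454 with an estimated correlation). The median standardised difference was 1.48. No member passed over all genes, and 8 passed adjusted over the list alone, all higher. Idi1, the isopentenyl-diphosphate isomerase, differed by 0.0327 ± 0.00506 and Msmo1, a sterol methyl oxidase, by 0.0335 ± 0.00555. Sqle, the squalene epoxidase, differed by 0.0175 ± 0.00191, Tm7sf2 by 0.0313 ± 0.00619, Cyp51 by 0.00401 ± 6.74e-04 and Hsd17b7 by 0.00143 ± 3.75e-04. Nr0b2, a nuclear receptor that represses bile acid synthesis, differed by 0.0664 ± 0.0101 and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, by 0.0508 ± 0.0145. Bile acid synthesis and sterol export was not called as a list (camera adjusted p = 0.349, 17 of 28 higher), and Nr0b2 alone passed adjusted over the list alone.

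The hypoxia response list rose, with 32 of 41 measured members higher (camera adjusted p = 6.61e-08, and adjusted p = 0.00693 with an estimated correlation). Adjusted over the list alone, 10 passed, all higher, and none over all genes. Igfbp1, which binds insulin-like growth factors, differed by 0.115 ± 0.0146 and Egln3, an oxygen-sensing prolyl hydroxylase, by 0.00762 ± 0.00169. Narf (0.00319 ± 4.31e-04), Ankrd37 (0.00316 ± 5.69e-04), Bnip3 (0.00138 ± 3.73e-04), Ccng2 (0.00103 ± 2.06e-04), Kdm3a (5.15e-04 ± 8.95e-05) and Ndrg1 (3.88e-04 ± 7.45e-05) were also among the 10, as was Adm (1.29e-05 ± 3.13e-06), whose sign turned under quantile normalization without the Hamp probe set. Epo, the erythropoietin gene, differed by 3.48e-06 ± 2.11e-06, with a limma adjusted p of 0.599. Egln3 had means of 6.305 in iron-deficient and 6.297 in control livers, and Epo 6.349 in both. These means lie below the 25th percentile of the arrays (6.55), so expression of either gene above background was not shown. Glycolysis rose as a list, 18 of 25 higher (camera adjusted p = 0.00657), but not with an estimated correlation (adjusted p = 0.0666), and it turned lower under quantile normalization without the Hamp probe set (mean z difference -0.327). Pklr, the liver pyruvate kinase, differed by 8.42e-04 ± 0.00103 and the glucose transporter gene Slc2a1 by 2.57e-04 ± 9.64e-05. Aldoc (2.26e-05 ± 3.72e-06), Slc16a3 (1.84e-04 ± 3.03e-05) and Pgam1 (4.18e-05 ± 9.13e-06) passed adjusted over the list alone, and Aldoc turned lower under quantile normalization.

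Respiratory chain subunits fell as a list, with 59 of 68 members lower (camera adjusted p = 6.61e-08, and adjusted p = 0.00693 with an estimated correlation). The list turned higher under quantile normalization, but stayed lower, uncalled, when the Hamp probe set was left out of it. It was not called under median centring (adjusted p = 0.795), where a constant larger than most members' differences decides. The median standardised difference was -1.24. No member passed over all genes, and 7 passed adjusted over the list alone, all lower. Ndufb5 differed by -1.05e-05 ± 1.78e-06, Cox8a by -1.48e-05 ± 3.23e-06 and Atp5f1b by -1.50e-05 ± 3.50e-06. All 3 turned higher under quantile normalization, though not without the Hamp probe set, and, by their size alone, under median centring. Ndufc1 differed by -8.16e-05 ± 3.18e-05 and Uqcrc1 by -7.16e-05 ± 5.07e-05. Chaperones and degradation genes of the endoplasmic reticulum fell, 25 of 30 lower (camera adjusted p = 0.00224), as did gluconeogenesis and glycogen, 19 of 23 lower (0.00876), and fatty acid oxidation, 33 of 43 lower (0.00912). All 3 lists turned higher under quantile normalization, but stayed lower, uncalled, when the Hamp probe set was left out of it. Their adjusted p with an estimated correlation was 0.329, 0.0697 and 0.329. None of their members passed, even adjusted over the list alone. The chaperone list lost its call without iron-deficient replicate 1 (camera adjusted p = 0.0576) and fatty acid oxidation without iron-deficient replicate 3 (camera adjusted p = 0.315). Creld2 and Hyou1, endoplasmic reticulum chaperones, differed by -0.00323 ± 0.00180 and -0.00180 ± 0.00124. Pck1, the cytosolic phosphoenolpyruvate carboxykinase, differed by 0.00186 ± 0.00102 and Pck2, its mitochondrial form, by -6.83e-04 ± 1.71e-04. The fatty acid transporter gene Cd36 differed by 0.0515 ± 0.0143 and Pex11a by -0.0110 ± 0.00653.

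Markers of other liver cell types also differed. Endothelial cell markers rose, with 14 of 20 higher (camera adjusted p = 3.19e-05, and adjusted p = 0.0257 with an estimated correlation). They were not called under quantile normalization (adjusted p = 0.0959), but were when the Hamp probe set was left out of it. Stellate cell and fibroblast markers rose, with 15 of 22 higher (camera adjusted p = 1.11e-04, and adjusted p = 0.0257 with an estimated correlation), but were not called under quantile normalization (adjusted p = 0.318, or 0.104 without the Hamp probe set). Kupffer cell and macrophage markers rose, 17 of 19 higher (camera adjusted p = 0.00153), but not with an estimated correlation (adjusted p = 0.308) or under quantile normalization (adjusted p = 0.113). Adjusted over the list alone, 7 endothelial, 7 stellate and 2 Kupffer markers passed, all higher, and none over all genes. Flt1 (0.00246 ± 3.27e-04) and Stab2 (0.00225 ± 3.71e-04), both endothelial receptors, were among them, with Egfl7 (4.21e-04 ± 5.39e-05), Fcgr2b (7.94e-04 ± 1.47e-04) and Lyve1 (1.80e-04 ± 3.62e-05). Among stellate markers, Lrat, which stores retinol as esters, differed by 2.82e-04 ± 5.15e-05, Dcn by 0.00276 ± 6.23e-04, Col3a1 by 0.00199 ± 4.61e-04 and Timp1 by 8.60e-05 ± 1.50e-05. Lox (0.00578 ± 0.00290) and Lum (0.00384 ± 0.00194) did not pass. Lyz2, a lysozyme of macrophages, differed by 0.00597 ± 0.00142, Mrc1 by 1.66e-04 ± 3.98e-05 and Lgals3 by 3.37e-04 ± 1.58e-04. Several hepatocyte markers hardly varied between arrays, such as Alb at -5e-09 ± 6.94e-07, so a missing call does not show that they were unchanged. Hepatocyte markers were not called (camera adjusted p = 0.867, 6 of 17 higher), with Apoa1 at 2.45e-05 ± 5.11e-05 and Hnf4a at -1.21e-05 ± 1.02e-05. Neither were those of cholangiocytes (0.689, 7 of 14 higher, Anxa4 1.58e-04 ± 6.57e-04, Epcam -1.34e-04 ± 7.36e-05), lymphocytes (0.712, 15 of 27 higher, Ptprc 2.81e-04 ± 1.26e-04, Cd52 1.40e-04 ± 1.00e-04) and neutrophils (0.349, 8 of 11 higher, S100a9 0.00142 ± 9.29e-04, Lcn2 3.30e-04 ± 1.85e-04). Red cell and erythroid precursor genes, 18 of 27 higher, were not called (0.0848), with Alas2, the erythroid heme enzyme, at 0.00799 ± 0.00445 and Hba-a3 at -0.00753 ± 0.00553.

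No call was made for heme synthesis and breakdown, 10 of 23 higher (camera adjusted p = 0.839). Alas1, the rate-limiting heme enzyme of liver, differed by -0.00582 ± 0.00250 (limma adjusted p = 0.452), Hmox1, which degrades heme, by 1.19e-05 ± 2.74e-04 (0.995) and Abcg2 by -4.81e-04 ± 0.00119. Cpox passed adjusted over the list alone at 2.16e-04 ± 3.75e-05, but turned lower under quantile normalization without the Hamp probe set. Iron-sulphur cluster assembly, 10 of 24 higher, was not called (camera adjusted p = 0.971), with Bola1 at -3.74e-05 ± 1.93e-05 and Fdx1 at -3.62e-05 ± 2.78e-05. For this list and for apoptosis the median standardised difference, -0.131 and -0.0345, had the opposite sign to camera's direction. Growth hormone and IGF genes, 16 of 29 higher (camera adjusted p = 0.0848), included Cish, a feedback inhibitor of cytokine signals, at -0.279 ± 0.0900 and Obp3 at 0.0255 ± 0.00441, which passed with Igfbp1 adjusted over the list alone. Immediate early genes, 16 of 28 higher (camera adjusted p = 0.0848), included Egr1 at 0.123 ± 0.0619, and Myc at -0.0331 ± 0.00455 and Klf4 at 0.00228 ± 4.59e-04, which passed adjusted over the list alone.

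Cell cycle genes, 23 of 54 higher (camera adjusted p = 0.322), included Ccnd1, the cyclin of early G1, at -0.290 ± 0.0491, which passed adjusted over the list alone, and Mcm6 at -0.00418 ± 0.00163. The other probe sets of Ccnd1 read -0.181 ± 0.0296 and -0.119 ± 0.0199, with standardised differences of -3.99, -4.12 and -4.03. Among oxidative stress genes, 16 of 46 higher (camera adjusted p = 0.111), Nqo1 differed by 0.0127 ± 0.00415 and Me1 by -0.00321 ± 0.00571. Copper and zinc handling, 14 of 28 higher (0.653), held Mt2A, a metal-binding metallothionein, at 0.187 ± 0.0494 and Slc30a1 at 0.00410 ± 0.00208, while Slc39a4 (-2.91e-04 ± 5.06e-05) and Atox1 (-1.81e-04 ± 3.34e-05) passed adjusted over the list alone. Fatty acid and triglyceride synthesis, 16 of 33 higher (0.788), held Elovl6 at -0.0163 ± 0.00695 and Pnpla3 at 0.0184 ± 0.0295. Drug-metabolising cytochrome P450 genes, 18 of 44 higher (0.867), held Cyp3a9 at 0.158 ± 0.0932 and Cyp17a1 at -0.136 ± 0.0637. Cyp1a2 (0.0194 ± 0.00242), Cyp2f4 (-0.00160 ± 2.05e-04) and Cyp4b1 (-8.65e-04 ± 1.16e-04) passed adjusted over the list alone. Amino acid breakdown and urea cycle genes, 36 of 69 higher (0.853), held Oat at 0.0307 ± 0.00709 and Bhmt, a methyltransferase of homocysteine, at 0.0227 ± 0.00259, of which Bhmt passed adjusted over the list alone. Acute phase genes, 26 of 36 higher (0.444), held Cxcl1 at 0.0829 ± 0.0743 and Cd14 at 0.00344 ± 0.00326. Integrated stress response genes, 19 of 41 higher (0.863), held Ddit4 at 0.00206 ± 6.43e-04 and Psat1 at 8.52e-04 ± 6.96e-04, and Eif4ebp1 passed adjusted over the list alone at -5.84e-05 ± 6.54e-06. Apoptosis genes, 21 of 43 higher (0.867), held Casp12 at 0.00215 ± 9.95e-04 and Gadd45a at -0.00191 ± 5.83e-04, and Htra2 passed adjusted over the list alone at -1.33e-05 ± 1.58e-06. Clock genes, 10 of 23 higher (0.712), held Lpin1 at -0.00142 ± 0.00158 and Noct at -0.00139 ± 0.00272. Per1 (-4.97e-04 ± 8.38e-05) and Npas2 (5.52e-05 ± 1.11e-05) passed adjusted over the list alone. Npas2, with a mean of 6.235 in both groups, lies below the 25th percentile of the arrays (6.55), so its expression above background was not shown. Atox1, Eif4ebp1 and Htra2 turned higher under quantile normalization, and Eif4ebp1 and Htra2 also without the Hamp probe set.

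None of the 57 control probe sets passed in limma, and 2 had an unadjusted p under 0.05. As a sign of RNA quality, the 3' to 5' difference on the log2 scale was 1.407 ± 7.95e-04 in iron-deficient and 1.408 ± 8.89e-04 in control livers for actin (SD, n = 4 each, exact permutation test, two-sided p = 0.114). For Gapdh it was 1.16963 ± 3.44e-05 and 1.16974 ± 8.63e-05 (exact permutation test, two-sided p = 0.0571), and the smallest p these tests can give is 0.0286. Both measures had the lower mean in iron-deficient livers. Differences between arrays are compressed in these values, so the measures cannot exclude a difference in RNA quality.

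**Figure D1:**
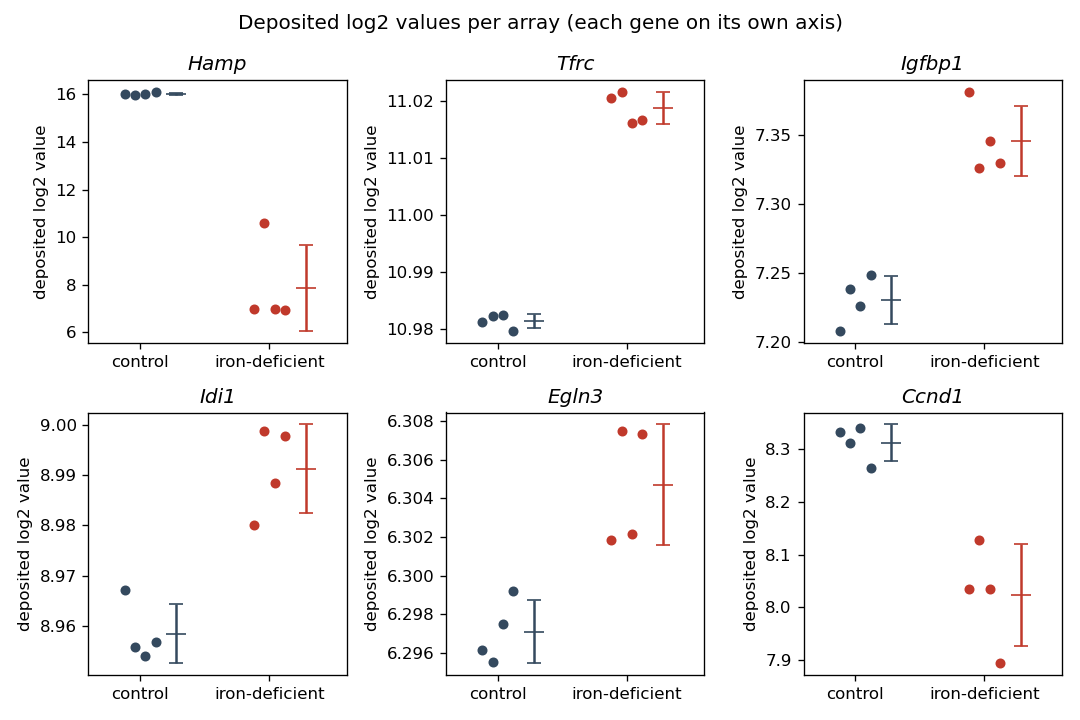
Deposited log2 value of Hamp, Tfrc, Igfbp1, Idi1, Egln3 and Ccnd1 in each of the 4 control (grey) and 4 iron-deficient (red) livers, each gene on its own vertical axis, with the mean and SD beside the points. Hamp of iron-deficient replicate 2 lies at 10.58, above the other 3 arrays of its group and below all 4 control arrays. Egln3 lies below the 25th percentile of the arrays (6.55), so its expression above background was not shown.

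**Figure D2:**
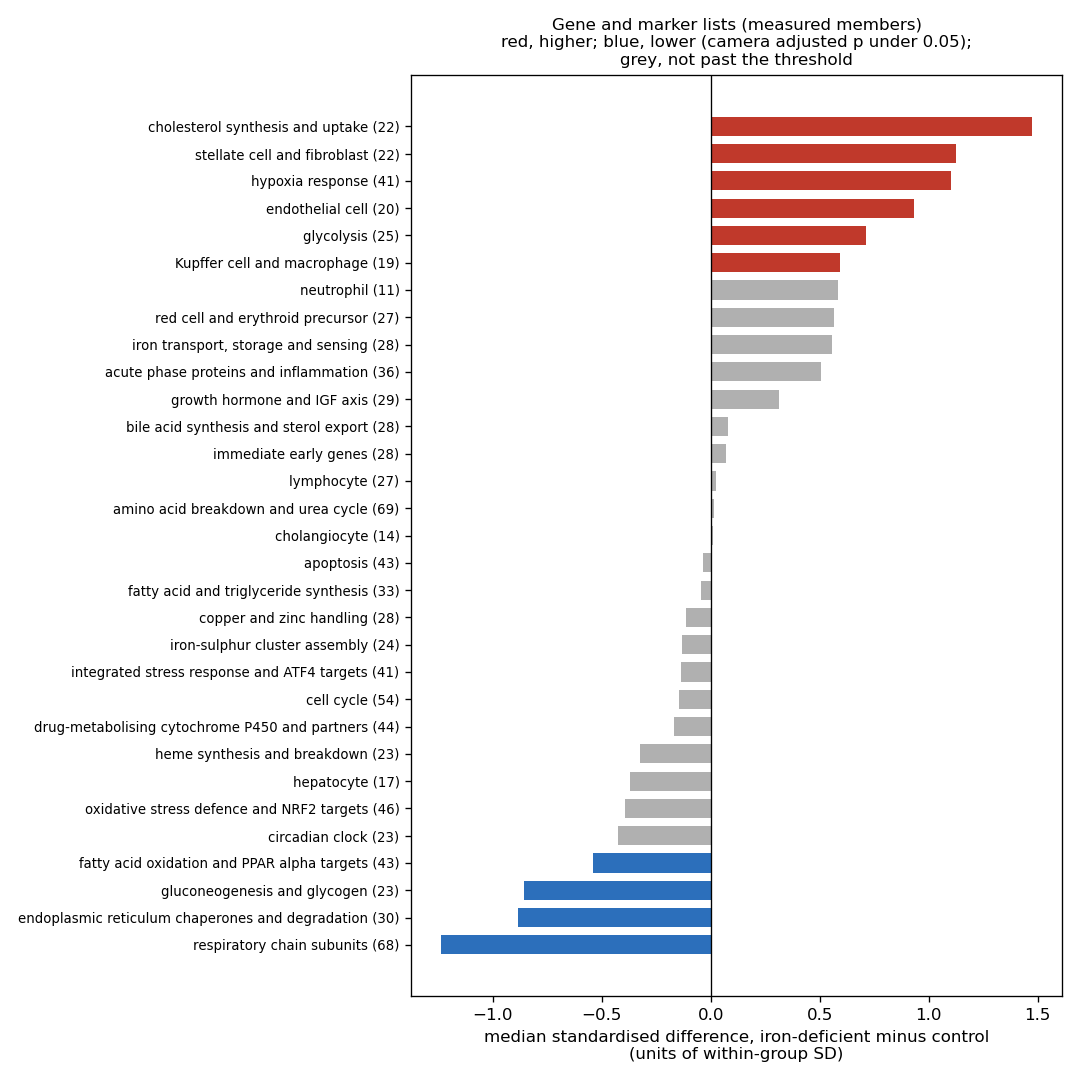
Median standardised difference of the measured members of 31 gene and marker lists, in units of the within-group SD, iron-deficient minus control, with the number of members in brackets. Red and blue bars are the 6 higher and 4 lower lists that passed in camera as deposited, from 1.48 for cholesterol synthesis to -1.24 for respiratory chain subunits. The latter turned higher under quantile normalization, but stayed lower, uncalled, when the Hamp probe set was left out of it.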

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

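The tests on Hamp and on the share of hepatocytes were chosen after the result was seen. Those on splits of the arrays and on lists of the same level were planned before. For single lists they were run only on those that camera had called, so which lists were tested depended on the result. In 18 of 238 groups of 4 values examined, the highest or lowest array stood far from the others, where chance gives about 1 in 20, or 11.9. The number given below is that array's gap to its nearest neighbour divided by the range of the group.

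Hamp of iron-deficient replicate 2 stood apart at 10.58 against 6.99 for the next array, a gap ratio of 0.984. A control liver under the wrong label is argued against: over 200 probe sets chosen without this array and without Hamp, it lay at 0.778 on an axis from the control mean (0) to the iron-deficient mean (1) of the other arrays. Control arrays, each left out in turn, lay at 0.391 at most. A small share of control RNA in the sample cannot be told apart from a true difference between rats. The size of such a share could be read only from plain log2 values, which the compression speaks against, and unsaturated controls, which was not tested. On that footing Hamp would need a share of 2.11%, less than the SD of 6.81% between the other 3 arrays on the Tfrc scale. There this array lay at 1.10 of the way from control to iron-deficient. Tfrc and Hamp may be compressed by different amounts, so these values do not decide the question.

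Among control arrays, replicate 4 stood high for Alas2 (8.19, gap ratio 0.885), Cd52 (6.53, 0.872), Adm (7.10, 0.836) and Alox15 (7.54, 0.879). Control replicate 1 stood high for Msmo1 (9.24, gap ratio 0.913), Mcm6 (6.56, 0.850) and Pnpla3 (7.04, 0.848). Control replicate 3 stood low for Ankrd37 (6.89, gap ratio 0.881), Htra2 (8.79, 0.882) and Cyp17a1 (8.08, 0.832), and control replicate 2 for Abcg2 (8.01, 0.841). Iron-deficient replicate 2 also stood low for Lyve1 (10.66, gap ratio 0.909) and Cyp1a2 (11.62, 0.842) and high for Fbxl5 (8.96, 0.845). Iron-deficient replicate 4 stood high for Egr1 (7.68, gap ratio 0.918) and Ptprc (8.21, 0.885), and iron-deficient replicate 1 for Apoa1 (13.81, 0.878).

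Endothelial and stellate cell markers were higher in the iron-deficient livers. A lower share of hepatocytes, which would raise the markers of every other cell type alike, cannot be told apart from a change in these cells. Over markers of 1 type only and above the median level of genes, the mean z was 1.38 for 15 endothelial, 1.54 for 9 stellate, 1.11 for 17 Kupffer and -0.218 for 5 cholangiocyte markers, and a permutation test did not resolve a difference between these 4 types (p = 0.135). Lymphocytes and neutrophils kept 2 and 0 markers at that level, too few to include, and the 5 of cholangiocytes leave the comparison imprecise. A change in the amount or state of endothelial and stellate cells with diet also stays open.

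The lists that were lower as deposited hold abundant transcripts, and of 10 groups of genes by level, the 6 from a median level of 7.54 upward had a median z below 0. Among 10000 lists matched on level, the median of respiratory chain subunits lay at percentile 0, that of endoplasmic reticulum chaperones at 0.27 and that of gluconeogenesis and glycogen at 0.26. A shift shared by all genes of a level does not by itself give such medians. The matched lists were random draws of genes, so the percentiles do not allow for members that vary together. Such a shift with correlated noise in the list was therefore not excluded. For fatty acid oxidation, at percentile 3.4, a shift of the level cannot be told apart from a change of the list, since that percentile lies between the bounds set for either. The authors' normalization stays open as a source for all 4 lists. None was called in camera under quantile normalization without the Hamp probe set (adjusted p from 0.592 to 0.986), though all 4 stayed lower there. Each turned higher with that probe set included, but its change of rank shifts other probe sets. That turn therefore cannot show whether the authors' normalization is the source. Chance also stays open for all 4, and for 3 of them other splits of the arrays reached the real value.

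All 35 splits of the 8 arrays into 4 and 4 were fitted. For the count of probe sets only 1 split, the real one, gave as many as 10, and the highest other gave 1. For the count of genes only the real split gave as many as 6, and the highest other gave 1. Being 1 of 35 is the most extreme result these splits can give. Several counts and lists were tested without adjustment for their number, so chance was not excluded. The count of lists did not stand out, since 6 of the 35 splits gave at least 10. The highest other gave 13. For probe sets at an unadjusted p under 0.05, 1 split gave as many as the real 3539, and the highest other, with iron-deficient replicate 1 and control replicate 1 exchanged, gave 3515. Single lists were tested only where camera had called them on the real split, which favours that split. By the absolute mean z difference of these lists, only the real split, 1 of 35, reached the real value for cholesterol synthesis (1.91, highest other 1.48), hypoxia response (1.39 and 0.841), endothelial markers (1.44 and 1.18), stellate markers (1.29 and 1.03) and gluconeogenesis (0.893 and 0.763). At least 1 other split reached the real value for respiratory chain subunits (2 splits with the real one, 1.17 and 1.23), glycolysis (2 splits, 0.898 and 0.901), Kupffer markers (6 splits, 1.16 and 2.20), chaperones (5 splits, 0.927 and 1.38) and fatty acid oxidation (5 splits, 0.695 and 0.862).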

How the results depend on the processing

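Among the alternatives, the fits at a looser threshold of 0.1, camera on ranks and quantile normalization without the Hamp probe set were chosen after the data had been seen, and the others before. The cholesterol synthesis and hypoxia response lists kept their direction and their call under every alternative run on the lists, and the endothelial marker list under all but quantile normalization, where its adjusted p from camera was 0.0959. Tfrc kept its call in limma under all but the replicate block and the minimum of 1.5-fold, with a difference from 0.0345 to 0.0614. With the lowest 25% of probe sets left out, the counts were again 10 probe sets, 6 genes and 10 lists, but only 5 of the genes were shared, since Fgf23 was left out and Jam2 passed (limma adjusted p = 0.0480). A pseudocount alternative was not run, since the deposited values were already on a log2 scale, and Hamp has no value where its probe set was left out, nor Cd52, Egln3, Epo, Fgf23, Lum and Npas2 without the lowest 25%. Signal over background could not limit the list of tested probe sets, since no detection call was used here.

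Quantile normalization raised the counts from 10 to 1093 probe sets, 993 higher and 100 lower, and from 6 to 778 genes, 728 higher and 50 lower, with 15 lists past the threshold. Quantile normalization without the Hamp probe set gave 83 probe sets, 42 higher and 41 lower, 52 genes, 26 higher and 26 lower, and 4 lists, so most of the rise depended on this 1 probe set. Hamp leaves the top rank in the iron-deficient arrays, which shifts the rank of each probe set it passes. The 4 lists were cholesterol synthesis, hypoxia response and endothelial markers, which were higher, and cell cycle, which was lower. Median centring gave 63 probe sets, 52 higher and 11 lower, 38 genes, 32 higher and 6 lower, and 15 lists. The array medians span 7.40e-04, against a median within-group SD of 7.82e-06, so centring moves many small differences by more than their spread. Between the groups the mean of the array medians differed by -5.06e-05, which centring takes off every difference, so a smaller negative difference turns whatever its gene does. The median of all differences was -2.81e-08 as deposited.

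Differences in log2 that turned sign under quantile normalization were -3.07e-05 for Adora2a, -8.90e-05 for Aldoc, 3.32e-04 for Atox1, 0.00424 for Atp5f1b, -1.04e-05 for Bmp6, 5.57e-04 for Bola1, 0.00918 for Cox8a, 2.26e-04 for Eif4ebp1, 5.85e-04 for Epcam, -2.05e-04 for Epo, 0.00112 for Fdx1, 4.14e-04 for Higd2a, 6.72e-04 for Hnf4a, 4.52e-04 for Htra2, 0.00390 for Ndufb5, 0.00112 for Ndufc1, -1.74e-05 for Slc11a2 and 0.00174 for Uqcrc1. Those of the lists, as mean z minus that of other genes, were -0.143 for cholangiocyte, 1.19 for copper and zinc handling, 3.18 for drug-metabolising cytochrome P450 and partners, 2.73 for endoplasmic reticulum chaperones and degradation, 0.673 for fatty acid and triglyceride synthesis, 1.70 for fatty acid oxidation and PPAR alpha targets, 1.93 for gluconeogenesis and glycogen, 0.756 for heme synthesis and breakdown, 7.94 for hepatocyte, 0.229 for integrated stress response and ATF4 targets, -0.646 for lymphocyte, -1.05 for neutrophil, 1.56 for oxidative stress defence and NRF2 targets, -0.898 for red cell and erythroid precursor and 4.59 for respiratory chain subunits. Without the Hamp probe set, quantile normalization turned the sign to -3.54e-06 for Adm, -1.25e-04 for Adora2a, -1.71e-04 for Aldoc, -5.90e-05 for Bmp6, 1.27e-04 for Bola1, -1.09e-04 for Cpox, 4.60e-05 for Eif4ebp1, 4.72e-04 for Epcam, -2.05e-04 for Epo, 5.91e-05 for Higd2a, -2.92e-05 for Hmox1, 2.25e-04 for Htra2, -1.05e-04 for Slc11a2, -5.12e-05 for Slc2a1 and 2.27e-04 for Uqcrc1, and among lists to 0.0660 for circadian clock, 0.394 for copper and zinc handling, 0.0433 for drug-metabolising cytochrome P450 and partners, -0.327 for glycolysis, 0.311 for hepatocyte, 0.157 for integrated stress response and ATF4 targets, -0.138 for lymphocyte, -0.259 for neutrophil and -0.276 for red cell and erythroid precursor. Median centring turned it to 3.31e-05 for Arrdc1, 3.56e-05 for Atp5f1b, 1.32e-05 for Bola1, 3.58e-05 for Cox8a, 7.05e-06 for Fbxl5, 1.43e-05 for Fdx1, 2.39e-05 for Higd2a, 3.85e-05 for Hnf4a, 3.73e-05 for Htra2 and 4.01e-05 for Ndufb5, and among lists to -0.0580 for cholangiocyte, 0.210 for copper and zinc handling, 0.0127 for hepatocyte, 0.0339 for integrated stress response and ATF4 targets and -0.00168 for iron-sulphur cluster assembly. The mean of all probe sets of a gene gave 44 genes and 13 lists, and turned -1.17e-04 for Bmp6 and 4.94e-05 for Hnf4a, and among lists 0.00757 for drug-metabolising cytochrome P450 and partners and -0.00825 for iron-sulphur cluster assembly. The cause of these turns was not tested beyond the Hamp probe set and the array medians.

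Leaving out each array in turn gave from 4 to 27 probe sets, from 1 to 11 genes and from 9 to 13 lists. Probe sets numbered 5 without iron-deficient replicate 2, 27 without iron-deficient replicate 3, 4 without iron-deficient replicate 4, 6 without control replicate 2 and 4 without control replicate 3. Genes numbered 2, 11 and 1 without iron-deficient replicates 2, 3 and 4, and 2 and 3 without control replicates 3 and 4. The iron list passed camera without iron-deficient replicate 3 (adjusted p = 0.0162) and without control replicate 2 (adjusted p = 0.0291). Other lists not called with all arrays passed camera without iron-deficient replicate 2, at an adjusted p of 0.0103 for red cell and erythroid precursor, 0.0124 for oxidative stress defence and 0.0194 for cell cycle genes. Without control replicates 2 and 3 immediate early genes passed camera (adjusted p = 0.00763 and 0.0481), without control replicate 3 oxidative stress defence (adjusted p = 0.0304) and without control replicate 4 the red cell list (adjusted p = 0.00556). Differences whose sign depended on 1 array ran from -0.00102 to 6.59e-04 for Abcg2, from -3.11e-04 to 5.16e-04 for Anxa4, from -2.13e-05 to 4.51e-05 for Apoa1, from -1.70e-04 to 2.54e-04 for Hmox1, from -0.00717 to 8.10e-04 for Me1 and from -0.00267 to 0.0402 for Pnpla3. Another 25 of 118 named genes kept their sign but moved by over 1.5 times without 1 array or another, none of them past the threshold with all arrays, from 0.00133 to 0.00282 for Casp12, 0.00101 to 0.00539 for Cd14, 7.13e-05 to 2.12e-04 for Cd52, -0.00470 to -0.00193 for Creld2, 0.0143 to 0.126 for Cxcl1, 0.0724 to 0.205 for Cyp3a9, -1.74e-04 to -7.49e-05 for Epcam, 1.80e-06 to 4.74e-06 for Epo, -5.84e-05 to -1.61e-05 for Fdx1, -0.0100 to -0.00287 for Hba-a3, -1.76e-05 to -5.06e-06 for Hnf4a, -0.00290 to -9.80e-04 for Hyou1, 2.13e-04 to 4.58e-04 for Lcn2, 0.00353 to 0.00790 for Lox, -0.00237 to -4.50e-04 for Lpin1, 0.00198 to 0.00492 for Lum, -0.00494 to -0.00260 for Mcm6, -1.02e-04 to -5.17e-05 for Ndufc1, -0.00376 to -3.27e-05 for Noct, 9.93e-04 to 0.00238 for Pck1, -0.0151 to -0.00628 for Pex11a, 1.89e-04 to 0.00148 for Pklr, 1.96e-04 to 0.00125 for Psat1, 9.04e-04 to 0.00211 for S100a9 and -1.02e-04 to -3.77e-05 for Uqcrc1. Lists whose mean z difference changed sign ran from -0.0605 to 0.473 for acute phase proteins and inflammation, from -0.128 to 0.386 for amino acid breakdown and urea cycle, from -0.0444 to 0.158 for apoptosis, from -0.0874 to 0.400 for cholangiocyte, from -0.356 to 0.0164 for circadian clock, from -0.253 to 0.135 for drug-metabolising cytochrome P450 and partners, from -0.339 to 0.135 for fatty acid and triglyceride synthesis, from -0.256 to 0.00388 for hepatocyte, from -0.132 to 0.0983 for integrated stress response and ATF4 targets, from -0.107 to 0.177 for iron-sulphur cluster assembly and from -0.127 to 0.547 for lymphocyte.

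The replicate numbers did not pair the arrays. Deviations of same-numbered arrays correlated from -0.111 to 0.0245, those of other pairs from -0.149 to 0.169, and 1 of 4 correlated best with its own number. The replicate block left 1 probe set, 0 genes and 10 lists past the threshold, and the iron-sulphur cluster list at -0.0505, from a fit with fewer residual degrees of freedom. At an unadjusted p under 0.05 there were 3539 probe sets in limma and 3367 in the ordinary test. Trend and robust variances gave 8 probe sets and 4 genes, and the ordinary test without moderation 7 probe sets and 3 genes. A minimum of 1.5-fold left 0 probe sets and 0 genes in limma, where 2 probe sets exceeded that size at an unadjusted p under 0.05, since the deposited differences are compressed. An adjusted p under 0.1 gave 99 probe sets and 66 genes. Camera with an estimated correlation called 5 lists, fry 6 and camera on ranks 10. Fry gave the opposite direction for apoptosis (0.0474 in camera's measure) and iron-sulphur cluster assembly (0.0106).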

Other observations

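The genes named here and the test of vascular genes were chosen after values had been seen. At a looser adjusted p under 0.1 in limma, 66 genes passed, 39 higher and 27 lower. Several with known roles in vessels were higher: Jam2, a junction protein of endothelium, by 0.0235 ± 0.00217 (SE, n = 4 per group), Gja1, a gap junction protein, by 0.00337 ± 4.10e-04, Ramp2, which forms the adrenomedullin receptor, by 7.04e-04 ± 8.12e-05, and Ptprb, an endothelial phosphatase, by 1.93e-04 ± 2.46e-05. Adora2a, an adenosine receptor, was higher in both of its probe sets, by 0.00472 ± 3.21e-04 and 3.97e-05 ± 4.56e-06, though the second turned lower under quantile normalization. Alox15, a lipoxygenase, differed by 0.966 ± 0.121 and Rgs4, a regulator of G protein signals, by 0.0542 ± 0.00585.

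A hypothesis is that the higher endothelial markers may be part of a broader rise of vascular genes. It was tested on a list of vascular genes written after some of its genes had been seen. Members of any of the 31 lists and genes already past an adjusted p of 0.1 in limma were therefore left out, which left 60 genes. Of these, 38 were higher, with a camera p of 7.08e-04 at the preset correlation and 0.0109 with an estimated correlation, and 11 passed adjusted over the list alone, 9 higher and 2 lower. The list was drawn up by someone who knew the endothelial result, so the test is not independent of it. A lower share of hepatocytes would raise these genes too and stays open.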
